A study of Homo sapiens with 2 samples.

How the data were processed

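RNA-seq libraries of a human pancreatic cancer cell line were compared, 1 from untreated cells and 1 from cells treated with dihydroartemisinin (DHA). Each library was assigned to its group from its treatment label, which reads NC or DHA. NC is taken here as untreated, and that label alone does not say whether a vehicle was added. The deposited table holds whole-number read counts per gene for both libraries, with no normalization, and a column of gene lengths in bases. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with an Illumina TruSeq kit from 1 µg of RNA. The same protocol text names retina as the tissue, and the submitters' processing notes list the mouse genome build mm8. Both differ from the organism and cell line given in the other labels, and from the file headers and gene identifiers, which are human. All 58735 gene rows of the deposited counts had the identifier, coordinates, name and biotype of GENCODE release 29 on the human build GRCh38, and the deposited gene length equalled the union of exons in that release for all 58735. Coordinates are given on GRCh38. The aligner, the counting tool, its use of strand and of reads that map to several places, the DHA dose and the exposure time are not given in the sources used here.

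The libraries held 15452609 (untreated) and 14521101 (DHA) counted reads. Counts were scaled by the trimmed mean of M values (TMM; edgeR 4.0.16 in R 4.3.3), with factors of 0.996 and 1.00. The ratio of the DHA to the untreated library was taken after adding 0.5 reads to each count. A 95% counting interval of each ratio came from the exact Clopper-Pearson interval of the share of a gene's reads found in the DHA library. The distance from the middle to the end of the interval had a median of 0.62 on the log2 scale for genes with about 100 reads in both libraries together, and 0.19 at about 1000. Intervals cover counting error only, since reads copied by PCR are not independent molecules and variation between cultures was not measured. A count of 0 allows up to 3 reads, which is 0.195 CPM (reads scaled to a common library size) in the untreated and 0.206 in the DHA library. For a gene at 0 the fold was computed against 3 reads in that library.

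A gene was called higher or lower when it had at least 50 reads in at least 1 library, a ratio of at least 2-fold and an interval that excluded 1. This is a rule of size, and no p-value was computed. The rule, 35 gene lists with 813 entries, and the rule for naming genes were fixed before the data were examined. Of the list entries, 786 matched by symbol, 26 through older or newer symbols, and 1 histone gene did not match. For each list of at least 5 measured genes, the median log2 ratio was ranked among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. The random lists were drawn again for other scalings, read minimums and pseudocounts, for the trend removal and without genes that share exons. The rank describes these libraries and is not a test across replicates. The genes named are the 12 protein-coding genes with the highest lower bound of the ratio, the 12 with the lowest upper bound, and up to 4 members of each list with the largest absolute log2 ratio. Some genes that this rule takes are not reported here. Other genes were chosen after their values were seen. They are TXNRD1, GCLM, ABCC3, AKR1B10, FTL, FTH1, TFRC, GPX4, AIFM2, LPCAT3, FADS2, DDIT3, ATF4, LDHA, VEGFA, INSIG1, TNFRSF10A, BAK1, EPCAM, KRT8, KRT18, VIM, SNAI2, TNC, TGFB2, MMP14, ADAM17, PDGFB, LIF, RELA, RELB, ICAM1, OASL, OAS1, IFI6, PSMB8, PVR, CD274, DUSP9, LYZ, MT-RNR2, MT-ATP8 and the long non-coding RNAs.

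The size rule was tested on simulated counts with known folds for this comparison. With counting error alone, 100% of 100 genes planted at 3-fold were recovered and 1 of 11580 unchanged genes was called. With an assumed variation between cultures of 0.2 (coefficient of variation), 90% of the 3-fold and 99% of the 4-fold genes were recovered, and 2.15% of unchanged genes were called. With 0.4 these shares were 74%, 91% and 24.7%. Of 200 simulated lists of 25 genes, 84.5% with a planted shift of 0.6 on the log2 scale lay above the central 95% of random lists. Of lists with no shift, 7.5% lay outside it on either side. List members were drawn independently, so these shares need not hold for genes that vary together between cultures.

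Alternatives covered scaling by total reads, by DESeq2 1.42.0 size factors and by the upper quartile, other read minimums, pseudocounts and fold thresholds, protein-coding genes alone, and a stricter interval. Scaling without mitochondrial genes, removal of a trend on gene length and GC content, and leaving out genes that share over 50% of their exon length with another gene were added after the data had been seen. Of the genes with at least 50 reads, 137 share that much, and 32 of them were called. Their values are uncertain because the counting of shared reads is not given. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the other steps.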

Results

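The series addressed which genes respond to dihydroartemisinin (DHA) in pancreatic cancer, in connection with a prognostic gene signature and the tumour microenvironment. DHA is the active metabolite of the antimalarial artemisinins, and its endoperoxide bridge reacts with ferrous iron and heme. SUIT-2 is a human pancreatic adenocarcinoma cell line, here in a derivative with high metastatic potential. RNA-seq was done on untreated cells (label NC) and DHA-treated cells, with 1 library each. There are thus no replicates, and no difference below has a replicate check. Every statement of higher or lower compares these 2 libraries. The untreated library held 15452609 counted reads and the DHA library 14521101, with at least 1 read in 22903 and 22877 genes. Protein-coding genes took 97.4% and 96.9% of the reads.

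Among fixed gene lists, the median ratios of NRF2 targets, the ATF4 integrated stress response, immediate early genes, hypoxia and glycolysis genes and autophagy genes lay above those of random lists. Members at least 2-fold higher in the DHA library were 9 of 28, 14 of 30, 17 of 26, 13 of 29 and 11 of 28, and 2 NRF2 targets were lower. Within the hypoxia and glycolysis list, the 14 glycolytic enzyme genes had a median log2 ratio of only 0.08, with 3 higher. The medians of the epithelial, replication and fatty acid synthesis lists lay below those of random lists, with 14 of 19, 19 of 32 and 6 of 14 members at least 2-fold lower. PPP1R15A, which encodes the stress-response phosphatase subunit GADD34, was 19.05-fold higher (95% counting interval 16.5 to 22.2). The heme-degrading enzyme gene HMOX1 was 13.3-fold higher (11.4 to 15.7). CDH1, which encodes E-cadherin, was 37.6-fold lower (25.4 to 60.9), and the mucin gene MUC5AC was 59.6-fold lower (44.7 to 83.5). Of 12064 genes with at least 50 reads in at least 1 library, 811 (6.72%) were at least 2-fold higher and 1245 (10.3%) at least 2-fold lower in the DHA library. At least 4-fold, the numbers were 110 higher and 340 lower, but at 1.5-fold they were 2284 and 2320. With a minimum of 500 reads the excess turned, with 431 higher and 379 lower. The remaining 10008 genes did not pass the size rule. In simulated counts with an assumed variation between cultures of 0.2 or 0.4, 2.15% or 24.7% of unchanged genes were called. How much such variation adds to the 811 and 1245 calls was not measured. The median log2 ratio over all 12064 genes was 0.04, and upper-quartile scaling moved it by -0.10.

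**Figure D1:**
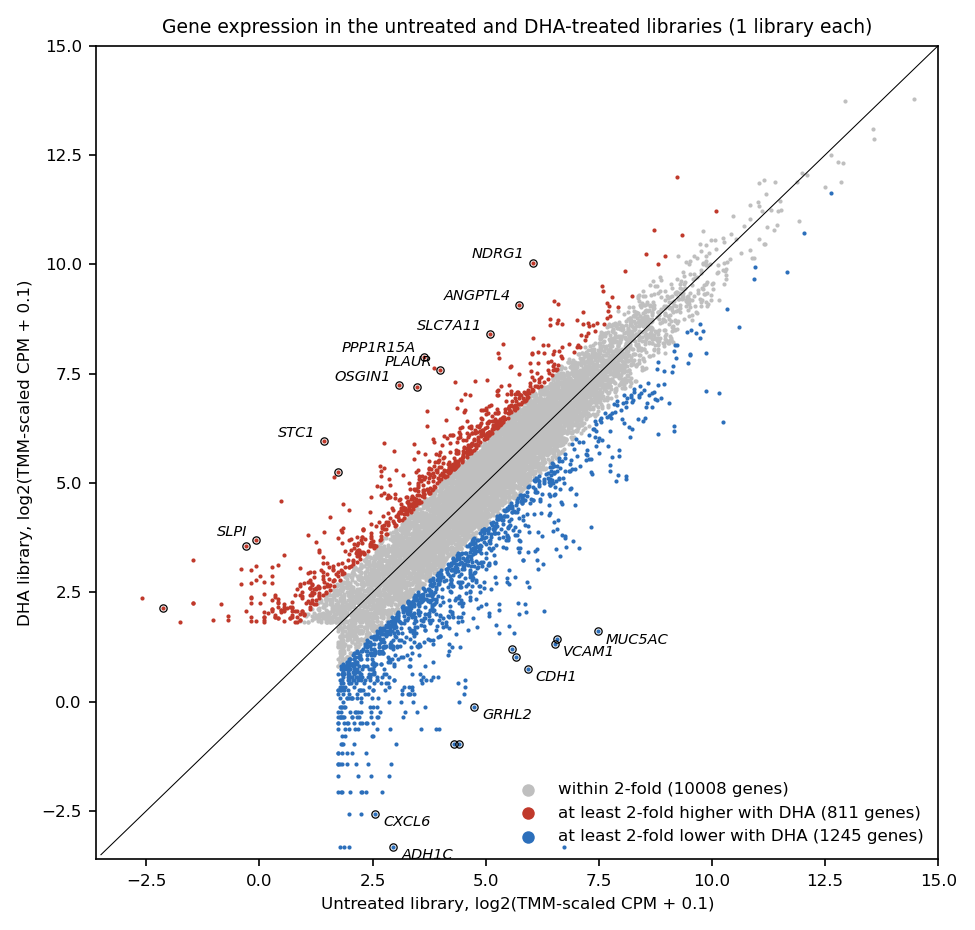
Level of each of the 12064 genes in the untreated library (horizontal axis) and in the DHA library (vertical axis), as log2 of TMM-scaled CPM plus 0.1, with 1 library per axis and the line of equal levels. The 811 genes called higher in the DHA library are red, the 1245 called lower are blue, and circles mark genes named by size.

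The genes with the most extreme ratios on the lower side included epithelial and secretory genes. The alcohol dehydrogenase gene ADH1C had 118 reads in the untreated library and 0 in the DHA library, at least 37.2-fold lower when 3 reads are taken as the floor. MUC5AC (ENSG00000215182, chromosome 11, 1157953 to 1201138, plus strand) had 2739 and 43 reads, and CDH1 (ENSG00000039068, chromosome 16, 68737225 to 68835548, plus strand) had 933 and 23. The chemokine gene CXCL6 had 89 reads against 1, a 56.5-fold lower ratio with a wide counting interval of 14.7 to 3365. The receptor gene EDAR was 47.4-fold lower (23.3 to 141), MACC1, a gene associated with metastasis, 43.8-fold (21.5 to 130), and the adhesion molecule gene VCAM1 37.7-fold (27.3 to 55.1). The amino acid transporter gene SLC38A4 was 35.8-fold lower, the epithelial transcription factor gene GRHL2 31.0-fold, the water channel gene AQP3 26.1-fold and PPP1R1B 21.4-fold.

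On the higher side, NDRG1, a gene responsive to hypoxia and metals (ENSG00000104419, chromosome 8, 133237171 to 133302022, minus strand), had 1014 reads in the untreated and 15302 in the DHA library, 15.9-fold higher (14.96 to 17.0). The secreted hormone gene STC1 was 23.7-fold higher (17.4 to 33.7), and OSGIN1, an oxidative stress gene, 17.8-fold (14.97 to 21.5). SRXN1, which encodes sulfiredoxin, was 15.8-fold higher (8.95 to 33.5), but 85.0% of its exon length is shared with another annotated gene on the same strand. The protease inhibitor gene SLPI was 14.6-fold higher, the urokinase receptor gene PLAUR 12.01-fold, the thrombomodulin gene THBD 11.6-fold and the lipase inhibitor gene ANGPTL4 10.1-fold. TM4SF19 had 2 reads against 63, a ratio of 26.8 with a counting interval of 8.84 to 281, and 49.6% of its exon length is shared with a readthrough gene. At least 100 reads in the untreated library against at most 3 in the DHA library were counted for 3 genes, among them ADH1C and the phosphatase gene DUSP9 (110 against 3). The opposite pattern was found for 0 genes.

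**Figure D2:**
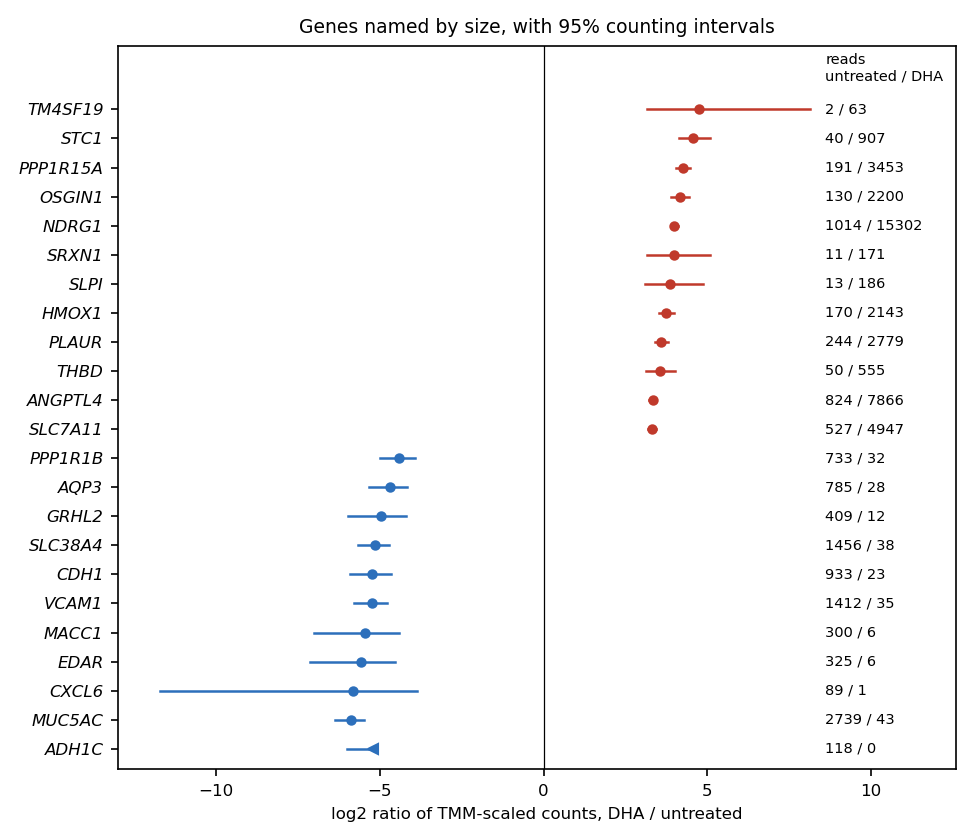
Log2 ratio of TMM-scaled counts (DHA over untreated) of genes named by size, with 95% counting intervals as bars and the reads of each library at the right. The left-pointing triangle marks ADH1C, with 0 reads in the DHA library, drawn at the bound that 3 reads give.

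NRF2 is the transcription factor of oxidative and electrophilic stress defence. Of 28 measured targets, 9 were at least 2-fold higher and 2 lower, and the median log2 ratio was 0.54, a value that 2 of 10000 random lists reached. Besides OSGIN1, SRXN1 and HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35394214, plus strand), the cystine transporter gene SLC7A11 (ENSG00000151012, chromosome 4, 138164097 to 138242349, minus strand) was 9.91-fold higher (9.06 to 10.9). TXNRD1, which encodes thioredoxin reductase, was 6.76-fold higher (6.61 to 6.91) at 59383 reads in the DHA library, and the glutathione synthesis gene GCLM was 4.40-fold higher. The lower members were the transporter gene ABCC3, 2.76-fold, and the reductase gene AKR1B10, 2.52-fold.

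The iron, heme and ferroptosis lists had medians within the central 95% of random lists, with members on both sides. Among 18 iron genes (median 0.12) the siderophore-binding LCN2 was 2.95-fold higher, and the ferritin receptor gene SCARA5 and the ferrireductase gene STEAP3 were 12.4-fold and 3.02-fold lower. The transferrin receptor gene TFRC had a log2 ratio of 0.85, and the ferritin genes FTL and FTH1 had 0.83 and 0.50, with 62.4% of the exon length of FTH1 shared with another gene. The iron regulatory protein gene ACO1 had -0.86. Among 16 heme genes (median -0.04) HMOX1 and HMOX2 (2.05-fold) were higher and 1 member was lower, the last 2 not under every scaling, and ALAS1, the rate-limiting enzyme gene of heme synthesis, had a log2 ratio of 0.90 (1.13 with the length and GC trend removed). Among 16 ferroptosis genes (median -0.03) 4 were higher, SLC7A11, the lipoxygenase gene ALOXE3 (9.51-fold, 7 against 67 reads), the glutathione-degrading CHAC1 (6.79-fold) and AIFM2 (2.30-fold). The desaturase genes SCD and FADS2 were 3.55-fold and 2.11-fold lower and LPCAT3 2.49-fold lower, the last with 65.6% of its exon length shared. GPX4, the lipid hydroperoxide reductase gene, had a log2 ratio of -0.44.

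Of 30 genes of the ATF4 integrated stress response 14 were at least 2-fold higher and 0 lower, with a median of 0.94 that 0 of 10000 random lists reached. VLDLR was 8.98-fold higher (7.34 to 11.2), CHAC1 6.79-fold (4.70 to 10.4), the pro-apoptotic transcription factor gene DDIT3 5.45-fold (4.85 to 6.15) and ATF4 itself 2.80-fold (2.66 to 2.94). The endoplasmic reticulum chaperones and XBP1 targets had a median of 0.21, within the random range. Of these 20 genes, 3 were higher, HERPUD1 (2.46-fold), SYVN1 (2.28-fold) and DNAJB9 (2.21-fold), all of endoplasmic reticulum quality control, and the disulfide isomerase gene PDIA4 had a log2 ratio of -0.77. Heat shock genes had a median of 0.55 (10 random lists as high), with DNAJB4, CHORDC1 and HSPH1 2.85-fold, 2.44-fold and 2.04-fold higher and the small heat shock protein gene HSPB1 4.55-fold lower among 18. HSPH1 was under 2-fold with DESeq2 size factors (log2 ratio 0.99), upper-quartile scaling (0.93) and the length and GC trend removed (0.88). The next list held metallothioneins, which bind zinc and copper, and the zinc exporter gene SLC30A1. Among its 7 measured genes, MT1X and MT2A were 4.43-fold and 2.33-fold higher and MT1A 2.56-fold lower. MT1M had a log2 ratio of -0.68, and the list median of 0.35 lay within the random range.

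Immediate early and AP-1 genes had the highest median of the 30 lists ranked, 1.17 (0 random lists as high), with 17 of 26 members higher (14 with upper-quartile scaling) and 0 lower. The MAP kinase phosphatase genes DUSP5 and DUSP6 were 7.88-fold (6.999 to 8.92) and 4.37-fold (3.90 to 4.93) higher, the AP-1 gene FOSB 7.76-fold (4.56 to 15.1) and the stress-induced ATF3 6.42-fold (4.70 to 9.13). Hypoxia and glycolysis genes had a median of 0.86 (0 random lists as high), with 13 of 29 higher and 0 lower. The 14 glycolytic enzyme genes among them had a median of 0.08, with 3 higher and 6 below 0. The 15 other members had 1.24, with 10 higher, in a split made after the values were seen. Besides NDRG1, the vasodilator peptide gene ADM was 7.79-fold (6.73 to 9.10), hexokinase gene HK2 6.93-fold (6.38 to 7.55) and ANKRD37 6.51-fold higher. The abundant lactate dehydrogenase gene LDHA had a log2 ratio of -0.94, with 60042 reads in the untreated and 29581 in the DHA library, and passed 2-fold lower with upper-quartile scaling (-1.05) and with the length and GC trend removed (-1.03). Autophagy and lysosome genes had a median of 0.59 (1 random list as high), with 11 of 28 higher and 0 lower. They included the autophagosome gene GABARAPL1 (5.002-fold), the autophagy receptor gene SQSTM1 (4.18-fold, 4.06 to 4.29), the kinase gene ULK1 (3.44-fold) and the lysosomal sialidase gene NEU1 (3.39-fold).

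**Figure D3:**
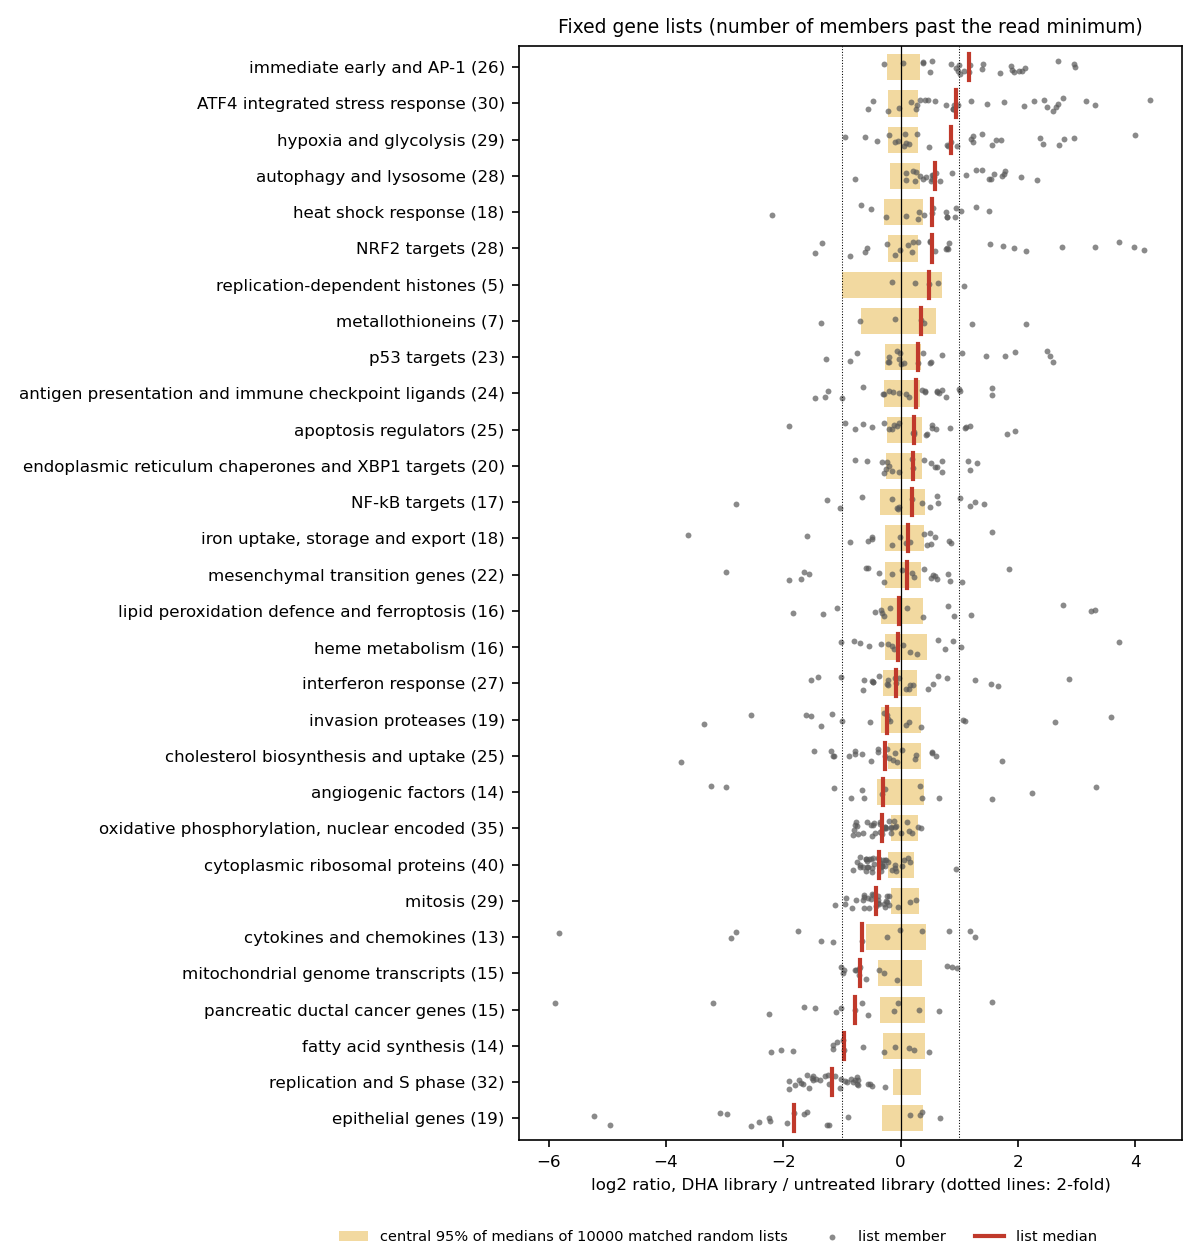
Log2 ratio (DHA over untreated) of each measured member of 30 gene lists as grey dots, with the list median in red and the central 95% of medians of 10000 random lists matched on expression as a shaded box. Medians run from -1.82 for epithelial genes to 1.17 for immediate early genes.

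Epithelial genes had the lowest median of the 30 lists ranked, -1.82 (0 of 10000 random lists as low), with 14 of 19 members lower and 0 higher. CDH1 and GRHL2 led, followed by the transcription factor gene ELF3 (8.48-fold, 7.22 to 10.1) and the tight junction gene TJP3 (7.77-fold, 5.25 to 12.4). EPCAM was 5.30-fold lower (4.64 to 6.10) and the keratin genes KRT8 and KRT18 2.39-fold and 2.34-fold lower. Pancreatic ductal cancer genes had a median of -0.77 (1 random list as low), with 7 of 15 lower and LCN2 higher. Besides MUC5AC, TSPAN8 was 9.20-fold (7.47 to 11.5), MUC1 4.73-fold (3.21 to 7.42) and KRT19 3.12-fold lower. Mesenchymal transition genes were mixed, with a median of 0.11 inside the random range. Of 22 genes, 2 were higher, among them SNAI2 (2.07-fold, under 2-fold with upper-quartile scaling), and 5 extracellular matrix and signalling genes were lower, THBS1 (7.83-fold), TGFBI (3.75-fold), FN1 (3.23-fold), TNC (3.13-fold) and TGFB2 (2.95-fold). The intermediate filament gene VIM had a log2 ratio of 0.24.

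Invasion proteases and their inhibitors also went both ways (19 genes, 4 higher, 6 lower, median -0.24, within the random range). PLAUR, the collagenase gene MMP1 (6.203-fold, 5.86 to 6.57), ADAM17 (2.15-fold) and MMP14 (2.10-fold) were higher, and the inhibitor genes TIMP3 and SERPINB5 were 10.2-fold (8.89 to 11.7) and 5.84-fold (4.67 to 7.46) lower. ADAM17 and MMP14 were under 2-fold with upper-quartile scaling (log2 ratios of 0.9997 and 0.97). With the length and GC trend removed ADAM17 had 0.97, and 3 members were higher. Angiogenic factors had 3 members of 14 higher, ANGPTL4, HBEGF (4.75-fold) and VEGFA (2.95-fold). The 3 lower members were the endothelin gene EDN1 (9.36-fold), PDGFB (2.19-fold) and THBS1, which encodes an inhibitor of angiogenesis. The list thus mixes factors of both kinds, and its median of -0.29 lay within the random range. The median changed sign, to 0.035, with a minimum of 1 read.

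Of 32 replication and S phase genes 19 were at least 2-fold lower and the other 13 did not pass the size rule, with all 32 log2 ratios below 0 and a median of -1.16 (0 random lists as low). The helicase subunit genes MCM3 and MCM6 were 3.74-fold and 3.33-fold (3.06 to 3.63) lower, the primase gene PRIM1 3.73-fold and the polymerase subunit gene POLE2 3.48-fold. Mitosis genes had a median of -0.41 (0 random lists as low), but of 29 members only the kinesin gene KIF20A passed the size rule, 2.16-fold lower, against 3 members with upper-quartile scaling. CENPF, TOP2A and CCNB1 had log2 ratios of -0.94, -0.92 and -0.83. Of 20 replication-dependent histone genes 5 had enough reads (median 0.48, within the random range), with HIST1H2BD 2.12-fold higher (under 2-fold with upper-quartile scaling) and HIST2H2BE, HIST1H2AC and HIST1H2BK at 0.64, 0.48 and 0.24.

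Among 23 p53 targets 7 were higher and 1 was lower, the higher ones including SESN2 (6.04-fold), the cell cycle inhibitor gene CDKN1A (5.87-fold, 5.38 to 6.42) and GDF15 (5.66-fold), and the list median of 0.29 was within the random range. With a minimum of 500 reads, 13 genes were left and their median of 0.52 lay above the random range (246 of 10000 random lists as high). With upper-quartile scaling (0.19) and with the length and GC trend removed (0.16) the median was smaller and within it. Of 25 apoptosis regulators 5 were higher, the death receptor genes TNFRSF10B (3.86-fold) and TNFRSF10A (2.15-fold), the anti-apoptotic MCL1 (3.52-fold), CASP9 (2.29-fold) and BAK1 (2.16-fold), and BMF was 3.75-fold lower. That list had a median of 0.24, within the random range.

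Of 14 fatty acid synthesis genes 6 were at least 2-fold lower (8 with DESeq2 size factors) and 0 higher, with a median of -0.97 (0 random lists as low). SREBF1, which encodes the transcriptional regulator of the pathway, was 4.63-fold lower (4.27 to 5.03), FASN 4.09-fold (3.97 to 4.21), SCD 3.55-fold (3.48 to 3.62) and FABP5 2.21-fold. Cholesterol genes had a median of -0.26 (122 random lists as low), with 5 of 25 lower. These included ACAT2 (2.78-fold), DHCR7 (2.28-fold) and INSIG1 (2.21-fold). CYP51A1 was 3.32-fold higher, at 21 against 67 reads. Over 50% of the exon length of ACAT2 and of CYP51A1 is shared with another gene.

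Respiratory chain and ribosomal protein genes had ratios mostly below 0. Of 35 nuclear-encoded oxidative phosphorylation genes 29 had log2 ratios below 0, with a median of -0.32 (7 random lists as low) and 0 genes past the size rule. The ATP synthase genes ATP5F1A, ATP5MC1 and ATP5F1C and the cytochrome oxidase gene COX7C had -0.81, -0.79, -0.77 and -0.76. Of 40 ribosomal protein genes 35 were below 0, with a median of -0.36 (2 random lists as low) and 0 past the size rule. RPL10A, RPSA and RPL27 had -0.81, -0.74 and -0.69, and RPS23 had 0.94, or 1.07 and past 2-fold higher with the length and GC trend removed. Transcripts of the mitochondrial genome took 8.57% of the reads in the untreated and 6.44% in the DHA library. Their median was -0.69 (3 random lists as low), or -0.38 (209 as low) after a trend on gene length and GC content was removed, with MT-ATP6 2.01-fold lower and MT-ND3 and MT-CO3 at -0.98 and -0.96, whereas the ribosomal RNA gene MT-RNR1 had 0.96. Which of these passed 2-fold depended on the setting, since MT-ATP6 was at -0.998 with total reads, and both MT-ND3 (-1.02) and MT-CO3 passed with DESeq2 size factors. With the trend removed 0 members were lower, MT-ATP6 being at -0.79, and 2 were higher, MT-RNR1 (1.27) and MT-ATP8 (1.04).

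For the immune-related lists, cytokines and chemokines had a median of -0.66 (145 random lists as low), with 6 of 13 lower and 2 higher. Besides CXCL6, the death ligand gene TNFSF10 was 7.43-fold (5.28 to 11.02), the neutrophil chemokine gene CXCL1 6.96-fold (5.42 to 9.19) and TNFSF15 3.36-fold lower, while CXCL2 and LIF were 2.42-fold and 2.26-fold higher. With a minimum of 500 reads only 3 of these genes were left and the median was 0.83, and with the length and GC trend removed it was -0.55, within the random range. NF-kB targets (17 genes, median 0.19) had NFKB2 (2.69-fold), CXCL2, RELB (2.28-fold) and RELA (2.03-fold) higher and CXCL1, TNFAIP2 (2.39-fold) and ICAM1 (2.05-fold) lower. Interferon response genes (27 genes, median -0.08) had IFI27 (7.29-fold), IRF7 (3.17-fold), RSAD2 (2.93-fold) and IFI6 (2.42-fold) higher, and IFIT1 (2.88-fold), OASL (2.64-fold) and OAS1 (2.02-fold) lower. Antigen presentation genes and checkpoint ligands (24 genes, median 0.26) had ULBP2 (2.96-fold) and MICA (2.94-fold), ligands of the natural killer cell receptor NKG2D, CD274 (2.01-fold, 26 against 50 reads) and PVR (1352 against 2567 reads) higher. TNFRSF14 (2.73-fold), VSIR (2.45-fold) and the immunoproteasome gene PSMB8 (2.35-fold) were lower. The medians of these last 3 lists were within the random range, but with a minimum of 500 reads the interferon list, then 11 genes, had -0.47, below its random range (145 random lists as low). With the trend removed its median changed sign, to 0.00064, with 2 lower members. RELA, CD274 and PVR were under 2-fold with DESeq2 size factors and upper-quartile scaling, ICAM1 and CD274 with a pseudocount of 5, and OAS1 and RELA with the trend removed.

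Markers of other cell types were low in both libraries. The 12 retina markers, measured because the labels name that tissue, summed to 5.98 CPM in the untreated and 4.53 CPM in the DHA library, and OPN1SW alone gave 61 and 49 of these reads. The 10 fibroblast markers summed to 11.4 and 2.40 CPM, with COL1A1 at 83 and 11 reads, and the 10 leukocyte markers to 2.34 and 1.78 CPM, with LYZ at 22 and 12 reads. The 12 acinar and endocrine markers summed to 0.195 and 0.755 CPM. The 10 endothelial markers summed to 30.6 and 12.8 CPM, nearly all from PECAM1 (280 and 54 reads) and ESAM (182 and 121 reads).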

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

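Scaling without mitochondrial genes, removal of a trend on gene length and GC content, and leaving out genes with shared exons were chosen after the data had been seen. No paired analysis was possible because each group has 1 library. A comparison on normalized values of the authors, set in advance, was not run, because the table used here holds counts. The number of genes at least 2-fold higher in the DHA library (811) and of genes at least 2-fold lower in the DHA library (1245) stayed within 1.5 times their value under every scaling, under a pseudocount of 5, over protein-coding genes, with an interval excluding a ratio of 1.5, and under the alternatives added later. They were 1432 and 2386 with a minimum of 1 read, 431 and 379 with a minimum of 500 reads, 2284 and 2320 at 1.5-fold, and 110 and 340 at 4-fold. The excess of lower calls was nearly gone at 1.5-fold and turned at 500 reads. More or fewer genes are tested with another minimum. Upper-quartile scaling moved the median of all genes by -0.10 and took the share of higher calls from 39.4% to 30.4%. It moved 17 list medians by more than the mean arm of their counting interval (distance from the value to its end), to 0.84 for ATF4, 0.75 for hypoxia, 0.49 for autophagy, 0.44 for NRF2 and for heat shock, 0.10 for endoplasmic reticulum, 0.020 for iron, 0.0034 for mesenchymal, -0.14 for ferroptosis, -0.34 for protease, -0.37 for cholesterol, -0.42 for oxidative phosphorylation, -0.46 for ribosomal protein, -0.52 for mitosis, -0.79 for mitochondrial genome, -1.08 for fatty acid and -1.27 for replication genes. DESeq2 size factors gave 0.50 for NRF2, 0.17 for endoplasmic reticulum, -0.40 for ribosomal protein and -0.73 for mitochondrial genome genes, and total reads gave -0.68 for the last. With a minimum of 1 read the medians of the angiogenic and heme lists changed sign, from -0.29 and -0.04, and were 0.035 for angiogenic, 0.10 for heme and -0.28 for ferroptosis genes. With 500 reads the median of cytokines and chemokines changed sign, from -0.66 to 0.83, with 3 genes left. Others then became 0.52 for p53, 0.50 for NRF2, 0.40 for iron, 0.025 for mesenchymal, -0.18 for ferroptosis, -0.38 for cholesterol, -0.47 for interferon and -1.43 for epithelial genes, with fewer genes in each. With the length and GC trend removed the medians were 0.67 for NRF2, 0.65 for heat shock, 0.29 for iron, 0.24 for endoplasmic reticulum, 0.082 for ferroptosis (a change of sign from -0.03), 0.00064 for interferon (from -0.08), -0.16 for angiogenic, -0.25 for oxidative phosphorylation, -0.38 for mitochondrial genome and -1.04 for replication genes. Without genes that share exons, ferroptosis had 0.11. Beyond the changes that the settings themselves make, the cause was not tested. Of 193 called genes in the ranked lists, 13 lost the call under upper-quartile scaling, 13 with the trend removed, 7 under DESeq2 size factors, 6 under a pseudocount of 5 and 2 under total reads. In the first 3 of these 12, 14 and 6 others gained a call, and 0 changed direction. Of 128 genes taken by the naming rule, 32 moved by more than the longer arm of their counting interval under upper-quartile scaling, 31 with the trend removed, 6 under DESeq2 size factors and 2 under a pseudocount of 5. Depth limits genes of few reads, where intervals are wide.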

Other observations

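The tests of read depth and of scaling were chosen after the results were seen, those of scaling in place of a comparison of 4 scalings set earlier that could not decide, and the families of transcription factors, the long non-coding RNAs and the split of the hypoxia list were also examined only then. Of 422 long non-coding genes with at least 50 reads, 40 were higher and 86 lower in the DHA library. Over all 12064 genes, 6.72% were higher and 10.3% lower. The long non-coding genes were not compared with genes matched on expression, so these numbers show no effect of being non-coding. LUCAT1, a stress-responsive long non-coding RNA, had 222 reads in the untreated and 2883 in the DHA library, 13.7-fold higher (95% counting interval 11.96 to 15.8). LINC02532 had 51 and 0 reads, and HOXA-AS2 154 and 15. Among 18 families of transcription factor genes, the 35 genes of basic leucine zipper factors had a median log2 ratio of 0.51. Of 10000 random lists 3 reached that median, and 11 of the genes were higher and 2 lower. The family includes ATF and AP-1 proteins. Some of their genes are also in the ATF4 and immediate early lists, so the rank of the family is not separate from theirs. The 414 C2H2 zinc finger genes had a median of 0.28, which 0 random lists reached, with 24 higher and 11 lower.

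Within the hypoxia and glycolysis list, the 14 glycolytic enzyme genes had a median log2 ratio of 0.08 with 3 higher, and the 15 other members had 1.24 with 10 higher. Along chromosome 19, 5 overlapping windows of 50 neighbouring genes between 49487554 and 55484487 had medians 0.41 to 0.66 above that of all genes. In that stretch 25 C2H2 zinc finger genes had a median of 0.78 and 65 other genes 0.23, against 0.26 for 389 zinc finger genes elsewhere. The stretch was picked by these same ratios, so its higher values follow in part from that choice and are not a separate result. The remaining 3 windows beyond 0.4 were lower ones on chromosomes 2, 4 and 5.

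The epithelial list had a median of -1.82 in the DHA library. A different cell line behind that library could carry gains and losses of whole chromosome arms. Of 1101 windows of 50 neighbouring genes, 0.727% lay beyond 0.4, below the limit of 1% set before the test. Chromosome medians lay between -0.07 and 0.12 of the median of all genes. These values argue against whole-arm differences that move medians by over 0.4. Whether 2 cell lines would differ by that much was not tested, so another line is not excluded. The share of 0.727% and the largest window (0.66) exceeded all 100 shuffles of gene order (at most 0.584% and 0.50). Neighbouring genes thus did share some of their ratios, and smaller copy number differences are not excluded. Loss of counts at low depth is argued against by the 12 epithelial genes with at least 500 reads in at least 1 library, whose median was -1.43. Another cell line, a subclone of the same line, different culture density and a response to DHA stay open as hypotheses. Each group has 1 library.

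Of 40 ribosomal protein genes 35 and of 35 nuclear oxidative phosphorylation genes 29 had ratios below 0, with medians of -0.36 and -0.32, while RPS23 had 0.94. Removal of the trend on gene length and GC content left the higher of these medians at -0.25, which argues against that trend as the whole cause. The other scalings raise all genes by at most 0.011 and decide nothing. A single factor moves a list and random lists matched on expression alike. Both list medians differed from theirs by -0.39 (2 and 7 of 10000 as low), a distance that no single factor can alter. That rank was known when the comparison was chosen, so it is not a separate test, and the level against 0 still depends on the scaling. A response to DHA may account for the pattern but was not tested, and a difference between cultures or library preparations stays open.

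The mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 had log2 ratios of 0.96 and 0.79, short of the size rule, while 12 of 13 mitochondrial messenger RNAs had ratios below 0, with a median of -0.70. A single scaling factor moves both kinds alike and leaves the distance of 1.49 between the lower ribosomal RNA and the messenger RNA median. No single factor can be the source of that distance, which follows from how scaling works and is not a separate test. More capture of RNA without a poly(A) tail in the DHA library would raise nuclear RNAs of that kind. The 38 genes taken as such had a median of -0.052 (bootstrap interval -0.81 to 0.35). These went both ways, with 18 small nucleolar RNAs at -1.10, 7 small nuclear RNAs at 0.56 and 12 histone genes at 0.29, and mostly few reads each. Counts per gene do not show whether a read came from RNA without a tail, so the set cannot decide. A capture difference and a DHA response cannot be told apart. With the trend on gene length and GC content removed, the median of all 15 mitochondrial transcripts was -0.38 (209 of 10000 random lists as low) instead of -0.69, so that trend may account for part of the lower level. After that removal MT-ATP8 had 1.04 and MT-ATP6 -0.79, although MT-ATP6 shares 6.90% of its exon length with MT-ATP8. How reads of overlapping genes were counted is not given, and an effect of counting was not tested. The 8 mitochondrial transfer RNAs with at least 50 reads had a median of 0.62, with 2 higher and 2 lower.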
